A study of Mus musculus with 3264 samples.

How the data were processed

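RNA was counted per gene in single wells, each meant to hold 1 mouse cell, with a primer that carries molecular barcodes. The labels name 2496 wells of the cell line mixture and 768 wells of PBMC. The deposited values are expected counts: molecule counts per gene and well, which the authors made before deposit and did not scale between wells. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and aligned with STAR to the mouse genome mm10. Their versions, the counter, the annotation, the sharing of molecules between genes and any filter on wells are not given in the sources used here. Of the positive values, 5.31% in the cell line table and 5.15% in the PBMC table were not whole numbers, so no model for whole counts was used, and values were rounded only for thinning.

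The cell line table lists 24781 genes (6392 of them at 0 in every well) and 1836 wells: 330 random, 319 target (126 leukemia, 120 T, 73 HPC), 179 FACS (66, 68 and 45) and 1008 time-lapse wells. The PBMC table lists 25051 genes (11937 at 0) and 346 wells. Totals per well ran from 10004.8 to 140363 (median 38156) in the cell line table and from 1013.98 to 7991.91 (median 2112) in the PBMC table. A well passed with at least 1000 detected genes (cell lines) or 300 (PBMC). The lowest cell line well had 2617 genes, so all passed, and 7 PBMC wells, the lowest with 235 genes, did not, which left 339 with a median of 998 genes. The protocol adds ERCC spike-in RNA, but neither table holds an ERCC row or a mitochondrially encoded gene, so neither could be used. Rn45s took 11.6% and 23.7% of all counts in the cell line and PBMC tables. For genes per well at equal depth, wells were thinned to 27000 and 1500 counts. The wells left out as too shallow after rounding were 62 random, 68 target, 92 FACS, 144 time-lapse and 61 PBMC wells.

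Groups were taken from the labels. Since each sample is 1 cell and the labels name no animal, donor or culture, no test was run between groups and no p-value, standard error or count of changed genes was taken from cells. Shares carry exact Clopper-Pearson 95% intervals and ratios of low counts exact binomial intervals, which cover counting error only. Counts were summed per plate and group (for comparisons between plates, where the plate held at least 5 wells of the type), scaled to a sum of 1e6 (CPM), and compared as log2 (CPM + 1). Cell types were compared within plates and averaged over plates. ALPS against FACS and time-lapse against random are differences of means over plates, with the range over pairs of plates. For ratios, a gene at 0 counts in 1 group was set to a floor of 3 counts over the group and is given as "at least". Where its log2 difference is printed instead, the size rests on the 1 CPM added. The spread of a comparison is the SD of log2 differences over its expressed genes.

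Named genes had at least 50 CPM and 30 counts in 1 group and the same direction on every plate (every pair of plates for ALPS against FACS, at least 85% of time-lapse plates on 1 side of every random plate). They were not spike-ins, mitochondrially encoded genes or predicted or Rik symbols. The 10 largest differences in each direction qualified, plus the members of the gene lists described. Some genes that met this rule are not reported here. Of the 33 gene lists, members with at least 10 CPM in 1 group were used, a member counted at 2-fold with the same direction on every plate, and each list's median was placed among 10000 random lists matched on mean expression.

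Wells were clustered with scanpy 1.11.5 and igraph 0.11.9: counts scaled to the median total, log1p, 2000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 0.3 (cell lines) or 1 (PBMC), seed 1. A cell line cluster took the name of the labelled type that made up most of its labelled wells, FACS labels included. The 6 clusters held 233 (HPC), 304 (T), 296 and 418 (leukemia), 267 (HPC) and 318 wells (no labelled well). Profiles were the mean log CPM of target wells of each type, a target well's own plate left out, and a well took the type with the highest Spearman correlation. By cluster the random wells were 100 leukemia, 119 T and 111 HPC, and the time-lapse wells 423 leukemia, 267 HPC and 318 without a name. By profile the time-lapse wells were 425, 317 T and 266. Line genes were at least 8-fold over both other types with at least 50 CPM on every plate, up to 50 per line, and a well was mixed at 20% of a second line's score. Cell cycle genes are given as the median share of counts per well. Other tools were python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

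PBMC clusters took the type of which the most markers (at least 3, and more than of any other type) had a count in at least 20% of the cluster's wells and at least 1.5 times as often as in other wells. This gave 201 T cell-like, 89 B cell-like, 28 NK cell-like and 21 unnamed wells. This naming rule was set after the data were seen and was changed once its first form had left 2 more clusters unnamed. Their 10 genes highest by fold held more markers of another type (H2-Aa, H2-Ab1 and H2-Eb1 of MHC class II, or Sox4) than of their own.

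The groups, comparisons, markers, lists, the named-gene rule and most alternatives were fixed before the data were examined. These choices came after: leading with the target plates alone and applying the named-gene rule to them, classing wells by cluster type or nearest target profile, the 24-well repeat, line genes from target plates, the spread as a summary, random against FACS and target wells, Rn45s and Mir6236 left out, time-lapse plates 1 to 8 and 9 to 16 apart, mixed wells left out, and which lists to describe. The other alternatives were TMM or median-of-ratios scaling, 10 CPM added, the mean of the cells' CPM, ribosomal protein genes left out, each plate left out in turn, other well filters, other Leiden resolutions and seed, and other folds.

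The computation was tested on simulated data: wells drawn from Poisson counts with 100 genes changed 2-fold and 100 changed 4-fold, each up or down. Median recovered log2 differences were 0.99 and 1.98 for T against leukemia on target plates, 1.00 and 1.97 on FACS plates, 1.01 and 1.98 for ALPS against FACS and 0.99 and 1.98 for time-lapse against random. Under the plate rule of each comparison, at least 99% of the genes changed 2-fold passed a limit of 1.5-fold. All genes changed 4-fold and none of the unchanged genes passed 2-fold. A list of 10 raised genes reached the 100th percentile, 98 of 100 random lists of unchanged genes fell between the 2.5th and 97.5th, and 828 simulated wells clustered fully by type. Variation between cells beyond Poisson was not simulated.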

Results

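Single mouse cells were placed in separate wells and their RNA was counted gene by gene. The cells came from a mixture of 3 cell lines, a leukemia line, a T cell line and a hematopoietic progenitor cell (HPC) line, or were peripheral blood mononuclear cells (PBMC) of C57BL/6J mice. Most wells were filled by ALPS, an automated system that images live cells and picks them one at a time, and the others by fluorescence-activated cell sorting (FACS). The labels list 3264 wells on plates of 96: cells picked at random from the mixture (4 plates), cells picked by type (4 plates, each with 36 leukemia, 36 T and 24 HPC wells, called target wells here), cells sorted by FACS (2 plates, each with 36, 36 and 24 wells), cells picked from the mixture after time-lapse imaging (16 plates) and PBMC (8 plates). Each well is 1 cell and the labels name no animal or culture, so each group counts as 1 sample. No p-value was computed. Intervals are exact 95% intervals for counting error only, and the spread over plates, a technical batch, is given beside the values.

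The deposited tables list values for 85.9% of the random wells (Clopper-Pearson interval 82.1 to 89.3, plates 78.1 to 90.6%), 83.1% of the target wells (78.9 to 86.7, plates 73.96 to 90.6%), 93.2% of the FACS wells (88.7 to 96.3, plates 90.6 to 95.8%) and 65.6% of the time-lapse wells (63.2 to 68.001, plates 56.3 to 85.4%). All of these passed the minimum of 1000 detected genes. Of the PBMC wells, 44.1% are listed and passed the minimum of 300 genes (40.6 to 47.7, plates 31.3 to 61.5%), and 7 more are listed but did not pass. No listed cell line well holds fewer than 10004.8 counts and no PBMC well fewer than 1013.98, so these shares are of wells listed and not of all wells that gave a library. The median well held 38194 counts in the random group, 35223 in the target group, 26843 in the FACS group and 42537 in the time-lapse group, with a range of 10005 to 140363 over all cell line wells, and 2147 in PBMC (1013.98 to 7992). Detected genes per well had medians of 5960, 5671, 5273 and 6073 in the 4 cell line groups in that order. After thinning to 27000 counts, which left out 62 random, 68 target and 92 FACS wells as well as the time-lapse wells below that depth, the medians were 5176, 5071, 5192 and 5124, and PBMC thinned to 1500 counts, with 61 wells left out, had 749.5. Rn45s, the ribosomal RNA precursor, took a median of 5.68% of the counts in FACS wells, 11.2% in target wells, 8.997% in random wells, 13.1% in time-lapse wells and 20.5% in PBMC wells.

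Target wells carried the RNA of the line on their label, and FACS wells did not follow their labels. Clustering of the 1836 cell line wells gave 6 clusters, of which 5 took the name of a labelled line. Of the target wells, all labelled leukemia (interval 97.1 to 100%), all 120 labelled T (96.97 to 100%) and 70 of 73 labelled HPC (95.9%, 88.5 to 99.1) fell in a cluster of their own line. The other 3 HPC-labelled wells, all on plate 4, fell in leukemia clusters (2 wells) and in the T cluster (1 well). Of the FACS wells, 33.5% did so (26.7 to 40.9), 29 of 87 on plate 1 and 31 of 92 on plate 2. The 66 wells labelled leukemia were 23 leukemia, 24 T and 19 HPC by cluster, the 68 labelled T were 24, 24 and 20, and the 45 labelled HPC were 16, 16 and 13. The cluster type instead repeated every 24 wells: the type at a position on 1 FACS plate named that of 87 of 87 wells of plate 1 and 92 of 92 wells of plate 2 at the same position of the repeat on the other plate (97.96 to 100% over both). By cluster the FACS wells were 63 leukemia (35.2%), 64 T (35.8%) and 52 HPC (29.1%). Plate 2 held 28 HPC wells where 24 were labelled HPC.

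**Figure D1:**
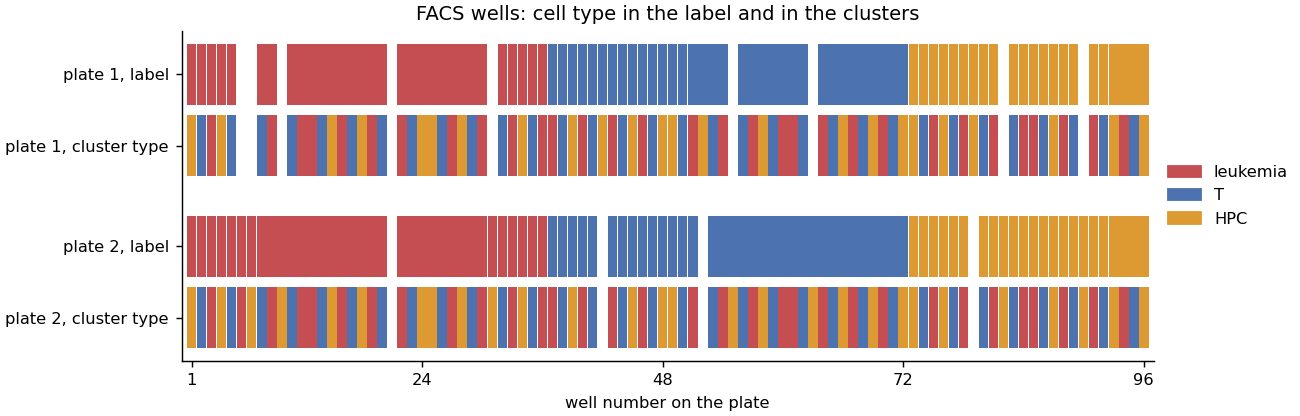
Each box is 1 well of a FACS plate in order of its number, coloured by the cell type in the label (upper line of each pair) or by the type of its cluster (lower line), and white wells are not listed. The labels run in 3 blocks of 36, 36 and 24 wells, while the cluster types alternate along the plate in the same order on both plates, and the 2 matched in 33.5% of the listed wells.

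T-labelled and leukemia-labelled wells were compared within plates, as the difference in log2 (CPM + 1), where CPM is a gene's share of the group's counts on a plate, scaled to 1e6. On the 4 target plates, T wells held more Thy1, a surface glycoprotein of T cells, with 600.2 CPM against 2.5 counts in all leukemia wells, a ratio of 1022.9 (interval 319.1 to 6156). They also held more Mt1, a metal-binding metallothionein (log2 difference 8.22, plates 7.31 to 9.42), Ly6a, a surface protein of lymphocytes and stem cells (7.54, 5.92 to 8.65), and Mt2, Fabp5, Chchd10 and Cdk6 (8.65, 8.41, 8.29 and 8.26, each with at most 3 counts in the leukemia wells). Leukemia wells held more Hmgn1, a nucleosome-binding protein (-8.29, plates -9.23 to -6.51), Cd7, a surface protein of early T and NK cells (-8.00, -8.57 to -7.31), and Cacna2d2, a calcium channel subunit (-7.45, -8.25 to -6.54). Cmah, which makes a sialic acid form, stood at 439.8 CPM in leukemia wells against 2 counts in T wells, a ratio of 1052.9 (291.1 to 8701). Cd160, a receptor of cytotoxic lymphocytes, stood at 378.1 CPM against 0.5 counts (-8.43), a ratio whose interval starts at 386.8.

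Of 11 measured genes of the T cell list, 6 were at least 2-fold higher in T wells in the mean over plates and higher on every target plate. Among them were Lck, the kinase of the T cell receptor (4.98), Bcl11b, a T lineage transcription factor (4.87), and Lat, an adaptor of the receptor (2.36). Cd28 (-3.23) and Cd3g (-3.20), subunits of the co-stimulatory and antigen receptors, were lower, and Cd3e (-0.27) and Tcf7 (0.31) were among the 3 that were neither. The list's median was 1.58, at the 100th percentile of 10000 random lists of like expression. Of 13 glycolysis genes, 4 were higher (Hk1 3.13, Aldoa 1.30, Pgk1 1.19, Ldha 1.07) and none was lower, with a median of 0.52 at the 99.8th percentile. Of 8 p53 targets, 4 were higher, led by Cdkn1a, an inhibitor of cell cycle kinases (6.88), and Zmat3 was lower (-1.39). Of 5 iron genes, Hmox1, which degrades heme (5.30), Fth1, the ferritin heavy chain (2.61), and Slc11a2, an iron transporter (1.36), were higher.

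The comparison planned over all 6 plates with labels kept gave smaller differences with wide plate ranges, since on the FACS plates the labelled types hardly differed. Led by Mt1 (5.57, plates 0.19 to 9.42) and Cmah (-5.64, -8.70 to -0.14), it kept 0 higher and 1 lower of the 11 T cell genes. The spread of the log2 differences over expressed genes, as their SD, was 0.97 over 6 plates, 1.52 on the target plates and 0.21 on the FACS plates by label. With FACS wells classed by cluster type, which rests on the same genes, it was 1.53.

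**Figure D2:**
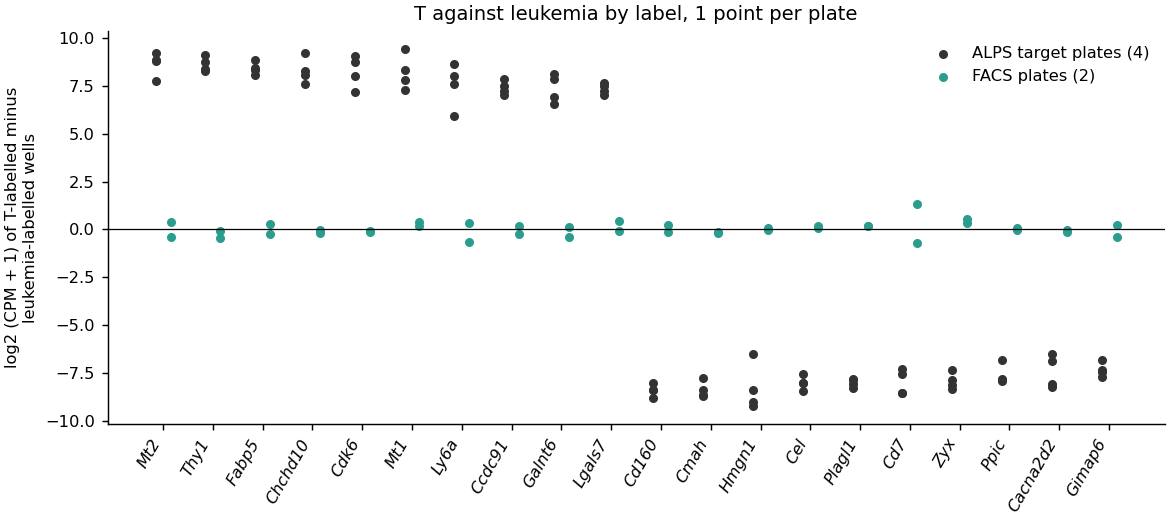
Log2 (CPM + 1) of T-labelled minus leukemia-labelled wells on each plate, for the 10 named genes highest and the 10 lowest on the target plates, with 1 point per plate. On the 4 ALPS target plates Thy1 lay between 8.27 and 9.10 and Cmah between -8.70 and -7.76, while on the 2 FACS plates the same genes lay between -0.71 and 1.32, both values those of Cd7.

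HPC-labelled wells differed from leukemia-labelled wells by the genes of hematopoietic progenitors. On the 4 target plates, Cd34, the progenitor surface antigen, stood at 516.99 CPM in HPC wells against 1 count in leukemia wells (ratio 2203, 394.6 to 87069). Sox4, a transcription factor of immature blood cells, stood at 306.99 CPM against 0 counts, at least 435.99-fold higher at a floor of 3 counts over the leukemia wells. Plac8, expressed in immature myeloid cells, was higher by a ratio of 2092 (578.4 to 17281), and Ccl3, a chemokine, and Mt1 were higher too (8.33, plates 6.54 to 9.05, and 8.33). Lower in HPC wells were Cacna2d2 (-7.27, -8.32 to -4.41), Cd160 (-7.13, -8.83 to -2.72), and Cd3g and Cd3e, antigen receptor subunits (-6.92, -8.41 to -3.05, and -6.56, -7.89 to -2.82). These plates include plate 4, where 3 HPC-labelled wells fell in clusters of the other lines.

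Of 14 progenitor genes measured, 13 were higher in HPC wells on every target plate, among them Flt3, a cytokine receptor (6.96), Spi1, the myeloid factor PU.1 (6.55), and Hoxa9 (6.47), and 1 was lower. Of 9 monocyte and macrophage genes, 7 were higher, such as Tyrobp, an immune receptor adaptor (8.23), and Lst1 (6.58), and Cx3cr1, a chemokine receptor, was lower (-5.26). None of 8 T cell genes was higher and 7 were lower. Of 10 p53 targets, 8 were higher (Cdkn1a 8.02, Pmaip1 6.26), and of 13 immediate early genes 6 were higher (Atf3 7.05, Jun 6.54, Fosb 4.07) and 2 lower (Nr4a1 -2.46, Egr1 -1.74). Flt3, Spi1, Hoxa9, Tyrobp, Lst1, Pmaip1, Atf3 and Jun had 0 counts in leukemia wells, so the size of their differences rests on the 1 CPM added. Medians were 5.25 for the progenitor, 4.84 for the monocyte, -4.56 for the T cell, 2.24 for the p53 and 0.72 for the immediate early list, at or beyond the 99.7th percentile or at the 0th. Over 6 plates with labels kept, 2 progenitor genes were higher and 1 lower, 1 monocyte gene was higher, 4 T cell genes were lower, and Cdkn1a led (5.45, 0.23 to 8.30). The spread was 1.004 over 6 plates, 1.61 on target plates and 0.23 on FACS plates by label.

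HPC-labelled wells also stood apart from T-labelled wells. Ifitm1, an interferon-induced membrane protein, was at 863.4 CPM in HPC wells of the target plates against 0 counts in T wells, at least 1377.9-fold higher. Plac8 (9.14, plates 7.55 to 9.74), Mef2c (8.26, 6.14 to 9.37) and Hmgn1 (7.99, 6.43 to 8.85) were higher, and Thy1 (-7.73, -9.30 to -3.26), Bcl11b (-7.05, -8.45 to -3.44), Lat (-6.67, -8.80 to -3.10) and Anxa2, a membrane-binding annexin (-6.64, -9.08 to -1.87), were lower. All 8 measured monocyte genes were higher, with Fcgr3, an Fc receptor, at 4.27 and Ccr2, a chemokine receptor, at 1 count in T wells (ratio 1659, 296.96 to 65597), and so were 11 of 14 progenitor genes, while Ly6a was lower (-5.08). Of 11 T cell genes, 9 were lower and Cd28 was higher (1.62). Of 12 integrated stress response genes, 8 were lower, such as Trib3, a pseudokinase (-2.52), and Asns, asparagine synthetase (-1.47), and of 10 p53 targets 7 were higher, such as Zmat3 (2.13). Medians were 4.42 (monocyte, or 4.48 with Itgam at 0 in T wells set to the floor), 5.37 (progenitor, or 5.70 with the 7 genes at 0 in T wells set to the floor), -5.13 (T cell), -1.14 (integrated stress response) and 1.10 (p53), at or above the 99.9th percentile or at or below the 0.01th. Over 6 plates with labels kept, none of 13 progenitor genes passed, 2 T cell genes were lower, 2 monocyte genes were higher, and 1 integrated stress gene, Ddit3, was lower. On FACS plates with wells classed by cluster type, 1 integrated stress gene was lower and 1 higher, so the 8 lower of the target plates did not recur. There 11 progenitor genes were higher and 1 lower, 11 T cell genes lower and 1 higher, and 9 monocyte and 5 p53 genes higher. The spread was 1.02 over 6 plates, 1.61 on target plates and 0.23 on FACS plates by label.

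The labels name the same 3 lines after ALPS and FACS isolation, on different plates. With labels kept, as planned, target wells lacked genes of the other lines that FACS wells carried. In leukemia-labelled wells, 10 of 12 progenitor genes were lower in ALPS wells, such as Cd34, with 1 count in ALPS wells (ratio 655.95 in favour of FACS wells, 116.8 to 26002). Plac8 was at 338.1 CPM in FACS wells against 2 counts (ratio 720.4, 198.6 to 5962), and Mt1 was lower (-7.87, plate pairs -8.91 to -6.45). In T-labelled wells 8 of 11 progenitor genes were lower and Ly6a was higher (1.14), and Ifitm1 was at 266.3 CPM in FACS wells against 0 counts (at least 424.95-fold). In HPC-labelled wells 9 of 10 T cell genes were lower, such as Thy1 (-6.20, -7.76 to -1.65) and Cd3e (-6.09, -7.53 to -1.99). The medians of these 3 lists were -4.24, -3.99 and -5.54, and -4.53 and -4.48 for the first pair with genes at 0 counts set to the floor. The spreads were 0.95, 0.91 and 0.92, against 0.30, 0.36 and 0.49 with wells classed by cluster type, a choice made after the label comparison was seen. With that choice Cd34 (0.24), Plac8 (0.13) and Mt1 (0.57) in leukemia wells, Ly6a (-0.21) in T wells and Cd3e (0.24) in HPC wells changed sign, as did Thy1 in HPC wells with random in place of target wells (0.18). Ly6a apart, FACS wells of the cluster type held at most 0.5 counts of each of these genes. Their values therefore mark a difference that was lost, not an opposite one.

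By cluster type, ALPS target wells differed from FACS wells in fewer and smaller ways. Leukemia wells held more Rgs2, a regulator of G protein signalling (2.70, plate pairs 2.33 to 3.04), Rn4.5s, a short structural RNA (1.94, 0.56 to 3.59), Klf6, a stress-responsive transcription factor (1.75, 0.68 to 2.63), and Malat1, a nuclear noncoding RNA (1.58, 0.85 to 2.19), and less Lrrc17 (-1.37, -1.49 to -1.23) and Dusp6, a phosphatase of ERK kinases (-1.17, -1.82 to -0.50). T wells held more Malat1 (1.28, 0.22 to 2.47) and more of the mitotic genes Top2a (1.18, 0.85 to 1.42), Kif20b (1.17, 0.73 to 1.62) and Cenpe (1.17, 0.53 to 1.76). Rnu11, a small nuclear RNA of the minor spliceosome, was at 70.8 CPM against 0 counts, at least 44.7-fold higher. Of 24 G2/M genes 4 were higher and none lower (median 0.40, 100th percentile), and of 9 immediate early genes Fos (4.65), Fosb (3.45) and Dusp1 (2.35) were higher.

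HPC wells from ALPS held more Atf3, a stress-induced transcription factor (4.12, 2.64 to 5.80), Fosb, a subunit of the AP-1 factor (3.45, 2.66 to 4.51), Rgs2 (2.49, 1.97 to 3.07) and Klf6 (2.48, 1.999 to 2.91). They held less Jchain, the joining chain of secreted immunoglobulins (-4.37, -7.35 to -0.76), Trib3 (-2.93, -5.06 to -0.45), the cytokine Tnf (-2.32, -3.30 to -1.71) and Myc, a growth-promoting transcription factor (-2.08, -3.36 to -0.77). The immediate early list had 4 higher and 1 lower (Ier3, -1.22) of 11. The integrated stress response list had 3 lower of 12, with a median of -0.93 at the 0th percentile, and the interferon list 3 lower of 9 (such as Irf7 -2.82 and Bst2 -1.15; median -2.06). Random HPC wells, compared with FACS in the same way, had 6 of 12 immediate early genes higher (Fosb 4.63, Fos 3.47, median 1.59), and compared with target HPC wells had 6 of 10 interferon genes higher. Among these, Rsad2, an antiviral enzyme, was at 95.5 CPM (plates 4.83 to 508.2) against 0 counts (at least 75.8-fold), and the list's median was 2.36, or 2.47 with genes at 0 set to the floor. ALPS and FACS wells share no plate, so method and plate batch cannot be told apart. Without FACS plate 2 the spread in HPC wells rose from 0.49 to 0.66, and 9 interferon, 8 integrated stress response and 4 immediate early genes were lower.

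The random wells hold the 3 lines in about equal parts. By cluster, 100 of 330 were leukemia (30.3%, 25.4 to 35.6), 36.1% T (30.9 to 41.5) and 33.6% HPC (28.6 to 39.02), but the plates ranged from 22.7 to 50.6% for T and from 24.1 to 42.7% for HPC. Of the time-lapse wells, 41.96% were leukemia (38.9 to 45.1, plates 24.1 to 54.5%) and 26.5% HPC (23.8 to 29.3, plates 15.2 to 40.7%). Nearly all of these HPC wells lay in cluster 4, which took its name from 1 labelled well, and nearly all of these leukemia wells in cluster 3, named from 6 target and 2 FACS wells labelled leukemia and 1 FACS well labelled HPC. No time-lapse well fell in the T cluster (0%, at most 0.365%), and 31.5% (28.7 to 34.5, plates 11.1 to 51.9%) formed a cluster of their own with no labelled well to name it. At Leiden resolution 1.0 instead of 0.3, 15.2% were HPC and 42.9% had no name. By the nearest of the 3 target-well profiles, all but 1 of those wells were T, and the time-lapse wells were 42.2% leukemia, 31.4% T and 26.4% HPC. The wells of named clusters had the same type by that profile in 99.9% of cases. The profiles use the variable genes of the clustering and target labels that also named clusters. This agreement is therefore not independent support for the names.

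**Figure D3:**
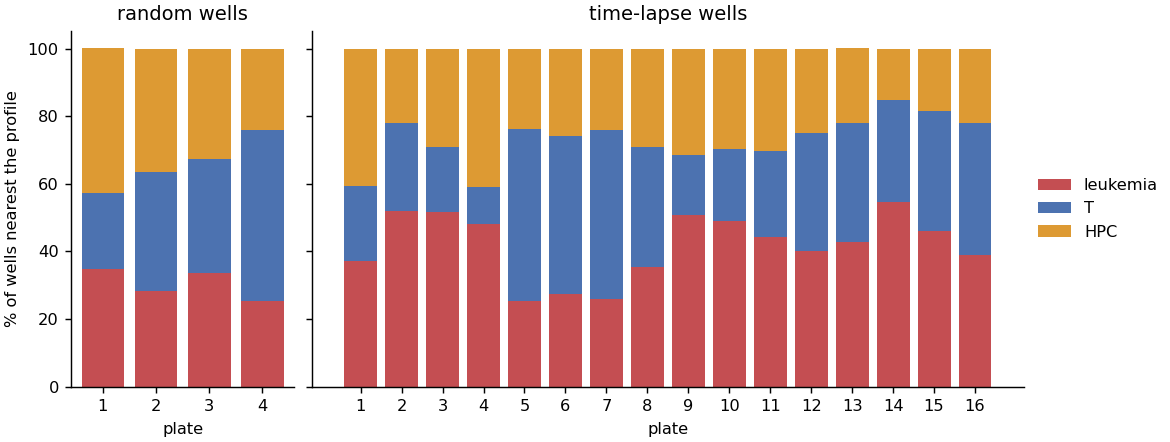
Percent of the listed wells on each plate that lay nearest the leukemia, T or HPC profile of the target wells, for the 4 random and the 16 time-lapse plates. The share of T ranged from 22.7 to 50.6% on the random plates.

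Time-lapse wells were compared with random wells within a line. HPC wells, nearly all in cluster 4 in the time-lapse group and cluster 0 in the random group, held more genes of the oxidative stress response. Hmox1 stood at 545.9 CPM (plates 79.6 to 1019.2) against 8.69 CPM (6.25 to 11.5; log2 difference 5.57), and Srxn1, which repairs peroxiredoxins, at 209.1 against 14.8 CPM (3.75). Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, stood at 642.2 and 608.6 CPM against 35.3 and 49.5 CPM (4.05 and 3.55). Of 10 genes of the list 7 were higher on at least 85% of the time-lapse plates, and Slc7a11 (1.25), Txn1 (0.25) and Sod2 (-0.60) were not. The median was 2.74 at the 100th percentile. Lower were the immediate early genes Fosb (-5.57, plate pairs -8.04 to -2.42) and Fos (-4.35, -6.68 to -2.24), and Ccnd1, the cyclin D1 of cell cycle entry (-4.56, -6.57 to -1.47).

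In the same HPC wells 9 of 12 cholesterol synthesis genes were lower, such as Lss (-2.52) and Sqle (-1.73), 1 was higher, and the median was -1.42. The interferon list had 8 of 10 lower (Usp18 -3.63, Isg15 -3.01, median -2.19), the immediate early list 5 of 12 (median -1.29), and the Myc and nucleolar list 6 of 10 (Myc -2.89, Nolc1 -1.88, median -1.24), all 4 lists at the 0th percentile. The random HPC wells used as the reference themselves stood above target HPC wells in the interferon list (median 2.36) and above FACS HPC wells in Fosb (4.63) and Fos (3.47). Fth1 (1.20) and Ftl1 (1.04), the ferritin chains, were higher, though on time-lapse plates 9 to 16 alone 1 iron gene was higher instead of 3. Tfrc, the transferrin receptor, was lower (-1.14). Under TMM or median-of-ratios scaling, or without Rn45s and Mir6236, Tfrc was lower on too few plates to count. The spread over genes was 0.73.

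Leukemia wells, in cluster 3 in the time-lapse group and cluster 2 in the random group, differed less, with a spread of 0.38. They held more Nfkbia, the inhibitor of NF-kB (1.99, plate pairs 0.11 to 4.26), Crebbp, a histone acetyltransferase (1.67, 0.97 to 2.88), Neat1, a nuclear noncoding RNA (1.65, 0.68 to 3.27), and Slc38a2, an amino acid transporter (1.51, 0.69 to 3.09). They held less Rpph1, the RNA of ribonuclease P (-3.52, -5.97 to -1.72), Cd69, an early activation antigen (-2.55, -4.08 to -0.72), Pfn1, an actin-binding profilin (-1.93, -3.32 to -0.86), and Txnip, a thioredoxin inhibitor (-1.78, -3.11 to -0.46). Of 7 oxidative stress genes 1 was higher, Gclc (1.54), with a list median of -0.07, and of 8 hypoxia genes Ankrd37 (3.02) and Vegfa, a vascular growth factor (1.21), were higher, with a median of 0.04.

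Wells nearest the T profile, in cluster 5 in the time-lapse group and cluster 1 in the random group, differed most, with a spread of 0.93, and the genes below are also among those that set these clusters apart. S100a6, a calcium-binding protein, was at 0.206 CPM in time-lapse wells against 689.8 CPM in random wells (-9.25, plate pairs -9.55 to -8.45). Thy1 (-6.97, -9.46 to -4.74), Lgals7, a galectin (-6.38, -7.69 to -4.59), Tesc (-5.85, -7.62 to -4.02) and S100a4 (-5.65, -9.81 to -3.87) were also lower. Pde2a, a cyclic nucleotide phosphodiesterase, was at 98.6 CPM against 0 counts, at least 187.3-fold higher, and Cd247, a signalling chain of the T cell receptor, at 52.8 CPM against 0 counts, at least 100.2-fold. Cd28 (4.59, 1.48 to 6.06) and Emb, a cell adhesion protein (4.38, 4.02 to 4.83), were higher. The T cell list had 6 higher (among them Cd8b1, 2.64, and Cd3d, 2.58) and 4 lower (Zap70 -5.15, Lat -1.74, Lck -1.44, Thy1) of 14, with a median of -0.08 at the 40.5th percentile. Ccna2, Plk1 and Cenpe of the 24 G2/M genes were lower (median -0.47, 0.3th percentile), as were 3 of 12 cholesterol genes, such as Msmo1 and Sqle (median -0.69), and Slc7a11 (2.41), Gclc (1.68) and Txnrd1 (1.05) of 9 oxidative stress genes were higher (median 0.07). Of the 22 T line genes found on target plates, 9 stayed within 2-fold in time-lapse T wells, 12 were lower and 7 of these by at least 8-fold, against 6 of 7 leukemia genes and 36 of 50 HPC genes within 2-fold in their own lines. Time-lapse and random wells share no plate, so imaging and culture cannot be told apart. In HPC wells of the same plates S100a6 stood at -0.05 (plate pairs -1.54 to 1.27). In leukemia wells, with 23.5 counts against 15.5, it stood at -1.29 (-2.72 to 0.40).

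Few wells held the RNA of more than 1 line. A well counted as mixed when a second line reached 20% of the summed score of line genes from the target plates, since no gene met the planned rule on the FACS plates. That held for 1 target well (0.313%, 0.00794 to 1.73), 1 FACS well (0.559%, 0.0141 to 3.07), 1 random well (0.303%, 0.00767 to 1.68) and 19 time-lapse wells (1.88%, 1.14 to 2.93, plates 0 to 5.56%). At a limit of 10% the shares were 2.19, 1.68, 0.606 and 3.17% in that order. The score rested on 7 leukemia, 22 T and 50 HPC genes. In time-lapse T wells 12 of the 22 T genes were at least 2-fold lower and 1 higher. T RNA is thus scored too low in time-lapse wells, and their share of mixed wells is less certain. The 19 mixed time-lapse wells held a median of 88284 counts and 8028 genes, against 42034 counts and 6058 genes in the others.

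Cell cycle genes took small shares of the counts, and S phase genes the smallest in HPC wells. S phase genes made up a median of 0.391% of the counts in leukemia, 0.380% in T and 0.276% in HPC wells of the target plates by cluster type, and 0.423%, 0.402% and 0.290% in random wells. In time-lapse wells the medians were 0.395% for leukemia (plates 0.278 to 0.437%), 0.323% for T by nearest profile (0.108 to 0.4254%) and 0.174% for HPC (0.0633 to 0.274%). G2/M genes had medians of 0.233%, 0.308% and 0.142% in target wells, 0.249%, 0.323% and 0.156% in random wells, and 0.211%, 0.198% and 0.106% in time-lapse wells. FACS wells had 0.198% for leukemia, 0.242% for T and 0.210% for HPC, where the 2 plates gave 0.0433 and 0.282%. As a share of the summed counts, time-lapse HPC wells held 0.247% G2/M genes against 0.313% in random HPC wells.

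PBMC wells were mostly lymphocytes by the markers fixed for naming. Of the wells that passed, 59.3% were T cell-like (53.9 to 64.6, plates 41.03 to 72.97%), 89 B cell-like (26.3%, 21.6 to 31.3, plates 16.2 to 38.5%) and 28 NK cell-like (8.26%, 5.56 to 11.7, plates 4.08 to 16.7%), and 21 stayed unnamed (6.19%, 3.88 to 9.31). With a stricter naming rule, used first and then dropped, the shares were 38.3% T cell-like, 8.26% B cell-like, 8.26% NK cell-like and 45.1% unnamed, and at Leiden resolution 0.5 instead of 1 they were 40.1% T cell-like and 28.6% NK cell-like. Cd79a, a chain of the B cell receptor, had a count in 92.9% and 98.4% of the wells of the B cell-like clusters and in 0 to 3.17% of those of the T cell-like and NK cell-like clusters. Tcf7, a T cell transcription factor, had a count in 55.2, 88.7 and 92.1% of the wells of the 3 T cell-like clusters and in 3.57 and 0% of the B cell-like ones, and Gzma, a cytotoxic granule protease, in 21 of the 28 NK cell-like wells and in 0 to 2.99% of T cell-like wells. Median counts were 2394 for T cell-like, 1854 for B cell-like, 1667 for NK cell-like and 1414.01 for unnamed wells. The unnamed cluster was led by Hmox1, Lpl, Clec4d and Cd14, of which the last marks monocytes, and Rn45s took 39.8% of its counts. Counted well by well, 7 wells held 3 or more classical monocyte markers (2.06%, 0.834 to 4.21), 44 held 3 or more NK cell markers (12.98%, 9.59 to 17.03), 52 held 3 or more markers of a dendritic cell list that includes H2-Aa, H2-Ab1 and H2-Eb1 of MHC class II (15.3%, 11.7 to 19.6), 1 held 3 neutrophil markers, and none held 3 platelet markers (0%, at most 1.08%). G2/M genes had 170.5 counts over all wells that passed, with a median of 0 per well.

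**Figure D4:**
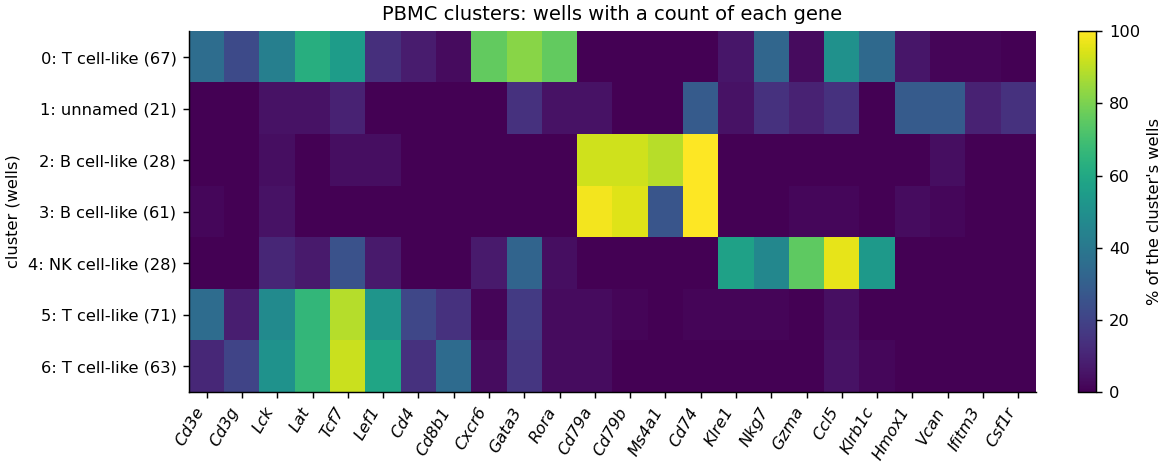
Percent of the wells of each PBMC cluster with a count of each gene, for 7 clusters with the number of wells in parentheses. Cd79a and Cd79b were found in over 90% of the wells of clusters 2 and 3, Gzma in 21 of the 28 wells of cluster 4, and Cxcr6, Gata3 and Rora in 76.1, 82.1 and 76.1% of cluster 0.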

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

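All tests of explanations in this part were chosen after the results were seen. Random, target and PBMC plates were looked at as 40 sets of values, some of which share wells. The 2 FACS plates and the 16 time-lapse plates were not looked at in this way. Of the 40 sets, 2 held a plate far from the others. That is no more than chance gives, about 1 in 20 sets for continuous values. On target plate 4 the median T-labelled well held 47422 counts, against 35614 to 36730 on the other 3 plates. On the same plate 83.3% of the HPC-labelled wells fell in an HPC cluster, against 100% on the others. With the other plates at 100%, any lower value would have been flagged.

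Some genes went one way on every plate of a group and the other way on every plate of another; the difference was not tested. By label, T against leukemia on target plates and, in parentheses, on FACS plates gave Cdk6 8.26 (-0.10), Chchd10 8.29 (-0.11), Thy1 8.62 (-0.29), Cel -8.03 (0.12), Plagl1 -8.02 (0.19) and Zyx -7.92 (0.42). HPC against leukemia gave Cel -6.84 (0.31), Chpf -6.24 (0.05) and Mef2c 9.001 (-0.51). Labels on the 2 FACS plates did not follow the types in the wells. Opposite signs on both FACS plates can therefore arise by chance and are no evidence of a difference between lines. With FACS wells classed by cluster type, which rests on the same genes, T against leukemia took the direction of the target plates. It was then 8.17 for Cdk6, 8.94 for Chchd10, 8.62 for Thy1, -8.50 for Cel, -8.43 for Plagl1 and -8.32 for Zyx.

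Time-lapse and random wells, compared within a line by nearest profile, also differed between lines; the difference was not tested. In leukemia wells Cd27, a co-stimulatory receptor, was at -1.19 (4.41 in T wells), Cd69 at -2.55 (1.95), Rgs2 at -1.28 (1.66) and Txnip at -1.76 (1.59). In T wells Dusp2, a phosphatase, was at 1.16 (-1.20 in HPC wells), Ftl1 at -0.32 (1.05), Napsa, an aspartic protease, at 5.50 (-0.70), Nqo1, a quinone reductase, at -0.68 (3.86) and Rgs2 at 1.66 (-1.46).

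The cell types found in FACS wells differed from their labels. With impure sort gates the types would fall into wells without order, but the 24-well layout of 1 FACS plate named the type of 100% of the wells of the other (97.96 to 100). RNA of several cells in each well would give many wells a second line's score of 20% or more, and 0.559% had one (0.0141 to 3.07). A repeating well layout that the labels do not follow needs over 90% of the wells to be named by the other plate, and 100% were, so it is a candidate explanation found and tested on the same wells. No biological explanation was tested, since the design gives none for a type that differs from its label.

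Time-lapse HPC wells held more oxidative stress RNA, such as Hmox1, Gclm and Srxn1. RNA of other lines in the wells would bring no more than those lines hold, yet the genes stood above the higher of the other 2 types on the same plates by a median of 1.49 (6 of 7 genes, the exception being Txnrd1). As the whole cause, an effect of the time-lapse plates on every well would raise leukemia wells alike, where the 4 genes measured had a median of 0.30, against 2.74 in HPC wells and an SD of 0.83 over the genes. Part of the response was shared: leukemia wells held more Gclc (1.54), and T wells more Gclc (1.68) and Txnrd1 (1.05). T wells also held more Slc7a11 (2.41), which did not count as higher in HPC wells. Gclm in leukemia wells (0.65) and Hmox1 (1.42) and Gclm (0.07) in T wells did not meet the rule for a higher gene. Nqo1 went the other way in T wells (-0.68), below the mean of the random plates on every time-lapse plate. The time-lapse handling or another HPC culture stay open and cannot be told apart, because 0 plates hold both random and time-lapse wells.

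Time-lapse T wells held little S100a6, Tesc and S100a4, which random T wells held. RNA of other lines in the wells would need them to make up most of a well, and the median share of a second line's score was 4.02%. An effect of the time-lapse plates on every well would lower these 3 genes in HPC wells too, where their median was -0.047 (-1.41 to 0.29), against -5.85 in T wells. That comparison cannot exclude an effect of the time-lapse handling on T wells alone. Such an effect, another T line or another culture state stay open. They cannot be told apart, because 0 plates hold both random and time-lapse wells.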

How the results depend on the processing

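The tests by cluster type, nearest target profile and stricter naming were chosen after the results were seen. For values that moved or reversed the cause was not tested, unless given. By replicate number, no paired analysis was possible because these numbers are only names in the order of deposit and each well is a different cell. Cell types were paired by plate.

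The spreads over genes kept within the variation between plates under TMM, median-of-ratios scaling, the mean of the cells' CPM, and ribosomal protein genes or Rn45s and Mir6236 left out. Of the named genes, 1, 3, 5, 6 and 1 moved under these and none reversed. The median of all genes shifted by -0.08 to 0.19 under TMM, -0.09 to 0.23 under median-of-ratios, -0.13 to 0.03 without ribosomal protein genes and -0.04 to 0.11 without Rn45s and Mir6236. With 10 CPM added, 98 named genes moved and none reversed, and by construction the spreads shrank: to 0.660, 0.639 and 0.703 for ALPS against FACS by label (leukemia, T, HPC), 0.299 (T) and 0.415 (HPC) by cluster type, 0.341 for random against FACS and 0.286 for random against target HPC, and 0.623 (HPC) and 0.735 (T) for time-lapse against random. With list genes counted at 1.5-fold instead of 2-fold, 9 of the counts changed by over 1.5 times, such as G2/M genes lower in time-lapse T wells (7 against 3) and higher in ALPS T wells (7 against 4). At 4-fold 21 did: in time-lapse HPC wells 1 cholesterol gene was lower instead of 9, 5 interferon genes instead of 8, 2 immediate early genes instead of 5 and 2 Myc and nucleolar genes instead of 6. Tfrc, the 1 lower iron gene there, stayed at -1.10 under TMM and under median-of-ratios scaling and at -1.07 without Rn45s and Mir6236, but no longer below every random plate on 85% of the time-lapse plates.

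On the FACS plates alone, by label, the spreads over the genes expressed on all 6 plates fell to 0.192 (T against leukemia), 0.227 (HPC against leukemia) and 0.230 (HPC against T). With FACS wells classed by cluster type they rose to 1.53, 1.74 and 1.75 over the genes expressed there, near the 1.52, 1.61 and 1.61 of the target plates alone, and 39 named genes moved. Over the genes expressed in the comparison by label, ALPS against FACS with labels replaced by cluster type had spreads of 0.303, 0.359 and 0.461 (leukemia, T, HPC), and 0.264, 0.357 and 0.383 with random in place of target wells; with each gene's difference averaged over the 3 types first, the spread went from 0.487 to 0.269. In leukemia wells Cd34 (0.24), Cdk6 (0.22, random wells 0.64), Chchd10 (0.49), Mt1 (0.57), Plac8 (0.13, random 0.0631), Thy1 (0.0135) and, in random wells, Fabp5 (0.0603) reversed. In T wells Cd34 (0.45, random 0.10), Cel (0.22, random 0.28), Ly6a (-0.21, random -1.06), Plac8 (0.18, random 0.12), Sox4 (0.45, random 0.28), Zyx (0.40) and, in random wells, Dynlt3 (-0.10) and Plagl1 (0.34) reversed. In HPC wells Anxa2 (0.37, random 0.84), Cd3e (0.24, random 0.14), Cpa3 (0.00702), Tcf7 (1.07, random 0.15) and, in random wells, Cacna2d2 (0.42), Cd3g (0.25), Lat (0.35) and Thy1 (0.18) reversed. Leaving aside Ly6a, Dynlt3, Cpa3 and Lat, FACS wells of the cluster type held at most 1 count of each reversed gene. For those genes a reversal is a difference lost near the lowest counts and not an opposite one. Of the genes that did not reverse, 54 moved with target and 57 with random wells.

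Leave-one-out over plates moved no named gene beyond the variation between plates. Leaving out 1 plate cannot shift a mean by the SD over plates, the limit used, so this shows nothing about stability. The spreads ran from 0.870 to 1.17 (T against leukemia), 0.886 to 1.21 (HPC against leukemia), 0.898 to 1.22 (HPC against T), 0.942 to 0.977, 0.895 to 0.959 and 0.881 to 1.02 (ALPS against FACS by label: leukemia, T, HPC), and 0.277 to 0.383, 0.354 to 0.456 and 0.476 to 0.655 (by cluster type). They ran from 0.407 to 0.553 for random against FACS and 0.323 to 0.356 for random against target HPC wells, and from 0.369 to 0.390, 0.927 to 0.938 and 0.713 to 0.750 for time-lapse against random (leukemia, T, HPC). Leaving out a FACS plate gave each highest value by cluster type against FACS. The random wells stayed at 29.02 to 32.1% leukemia, 30.9 to 40% T and 30.98 to 37.04% HPC. Of the counts of list genes at 2-fold, 40 changed by over 1.5 times, most of them over 6 plates by label. There, without FACS plate 1, T against leukemia had 2 T cell and 2 glycolysis genes higher (0 each with it) and 3 iron genes (1). HPC against leukemia had 7 progenitor (2) and 3 monocyte genes higher (1), and HPC against T 8 progenitor (0) and 3 p53 genes higher (1) and 5 T cell (2) and 4 integrated stress response genes lower (1). Without FACS plate 2, HPC against leukemia had 5 monocyte (1), 7 p53 (2) and 3 immediate early genes higher (1), and HPC against T 6 monocyte (2) and 3 p53 genes higher (1) and 5 T cell genes lower (2). By cluster type in HPC wells, ALPS against FACS without FACS plate 2 had 9 interferon (3), 8 integrated stress response (3) and 4 immediate early genes lower (1), and without target plate 1 or 2 it had 5 interferon genes lower. Mixed wells left out moved no named gene of time-lapse against random. Time-lapse plates 1 to 8 or 9 to 16 alone moved none either, but the same limit leaves little room for a move there. On plates 9 to 16 alone 1 iron gene was higher in HPC wells (3) and 5 G2/M genes lower in T wells (3).

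Against the profiles of FACS-labelled wells, agreement with the label fell to 10.3% (target leukemia), 1.67% (target T), 83.6% (target HPC), 23.8% (all target) and 6.67% (FACS HPC); those labels mix the lines. On those profiles the random wells were 30.3% T, and the time-lapse wells 21.3% leukemia, 40.8% T, 37.9% HPC and 0% without a name. By the nearest target profile the time-lapse wells were 31.4% T and 0% without a name, since each well takes a type. At Leiden resolution 1.0 they were 15.2% HPC and 42.9% without a name. Seed 2 and the cell cycle lists left out moved none of these shares. With a second line at 10%, 2.19% of target, 1.68% of FACS, 0.606% of random and 3.17% of time-lapse wells were mixed, and at 30% 0.313%, 0%, 0% and 1.49%.

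At resolution 0.5 PBMC wells were 28.6% NK cell-like and 40.1% T cell-like, while resolution 2.0, seed 2 and a minimum of 150 genes moved no share. With 600 genes needed, 0% stayed unnamed. Stricter naming gave 8.26% B cell-like, 38.3% T cell-like and 45.1% unnamed.

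Depth limits the genes per well: thinned, the medians fell to 5176 (random), 5045, 5142 and 4969 (target leukemia, T, HPC), 5123.5 (time-lapse) and 749.5 (PBMC). Cell cycle shares of summed counts were 0.479% for S phase in FACS leukemia, and for G2/M 0.293%, 0.347% and 0.246% in target leukemia, T and HPC, 0.248% in FACS leukemia, 0.310%, 0.351% and 0.313% in random leukemia, T and HPC, and 0.247% in time-lapse HPC wells.

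Not run: the ERCC scale and mitochondrially encoded genes, since the tables hold none. For cell line wells no filter and minimums of 500 and 2000 genes remove no well, so they show nothing about stability. No line gene met the planned rule on the FACS plates.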

Other observations

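The values in this part were chosen after the data were seen. Among the 3 T cell-like PBMC clusters, cluster 0 differed from clusters 5 and 6. It also met the naming limits for some NK cell markers, though for more T cell markers. At Leiden resolution 0.5 the NK cell-like share of all wells was 28.6% against 8.26%, and which wells changed name was not looked at. Cxcr6, a chemokine receptor, had a count in 76.1% of the wells of cluster 0 (interval 64.1 to 85.7), against 1.41% and 3.17%, and Rora, a nuclear receptor, in 76.1% against 2.82% and 3.17%. Gata3, a transcription factor of T cells and innate lymphoid cells, had a count in 82.1% against 16.9% and 15.9%. Ccr7, a lymph node homing receptor, had a count in 1.49% of the wells of cluster 0, against 45.1% and 49.2%. Thinned to 1500 counts, Cxcr6 stood at 66.2%, 0% and 3.23% and Ccr7 at 1.54%, 37.1% and 35.5%.

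By cluster type, ALPS target wells held less Lrrc17 than FACS wells in all 3 lines (-1.37 in leukemia, -0.77 in T and -2.16 in HPC wells), and less Maz, a zinc finger factor (-0.85, -1.14 and -1.22).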
